A study of Mus musculus with 12 samples.

How the data were processed

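Gene expression was measured in total RNA of 12 samples from female mice of the FVB strain aged 10 weeks, 6 from tumors and 6 from whole mammary glands, on a 1-colour mouse bead array that carries each probe on many beads. The labels gave 4 groups of 3 samples: tumors of PyMT mice (tumor control), tumors of PyMT/PANIC mice (tumor hyperglycemic), mammary glands of wild-type mice (mammary control) and mammary glands of PANIC-ATTAC mice (mammary hyperglycemic). Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase I treatment and labelled as biotinylated cRNA. The labels do not state whether the samples of a group came from separate animals, so every p-value measures the spread between these samples, which may be partly technical.

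The deposited table of non-normalized values held, for each of 45281 probes and each array, a mean bead intensity on a linear scale, a detection p-value, a bead number and a bead standard error. These bead intensities were summarised by the authors with GenomeStudio version 2011.1, per the submitters' processing notes, and the lowest value of an array lay between 27.7 and 30.5, so no value had been brought below 0 by a background subtraction. The detection p-values deposited by the authors compare each probe with the negative control beads of its array. A second deposited table held intensities whose quantiles were shared by all 12 arrays, with array medians from 57.2 to 57.3, on a linear scale and without centring per gene; the method behind it was not given in the sources used here, and it served only as an alternative.

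Between 20049 and 20880 probes per array (44.3% to 46.1%) had a detection p-value below 0.05. The median signal per array was 55.1 to 58.6 and the median number of beads per probe 37 to 44. The number of arrays, 3 per group, limits the precision of every mean. The 6 tumor arrays lay on slide 1 and the 6 mammary arrays on slide 2, so tissue and slide cannot be told apart. On each slide the control arrays took one block of positions and the hyperglycemic arrays the other, so position and genotype cannot be told apart either.

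Values were background-corrected, quantile-normalized over the 12 arrays and log2-transformed with neqc of limma version 3.58.1 in R version 4.3.3 (offset 16, background taken from the detection p-values). Probes with a detection p-value below 0.05 on at least 3 of the 12 arrays were kept, which left 22605 probes. A table of the platform's annotation gave 1 gene symbol to 34885 of the 45281 probes, several symbols to 18 and none to 10378, which are unnamed here. Symbols were looked up through Entrez numbers in a reference gene table, which held 34807 of the named probes and changed 0 symbols. Of a gene's kept probes, the one with the highest mean log2 value was used, which gave 11767 genes tested, 4776 of them with more than 1 kept probe. The 3651 kept probes without a single gene name were tested apart. The arrays name no genome build, so positions are not given.

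Differences were tested with limma (lmFit and eBayes) and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05, all two-sided. The hyperglycemic and control groups of a tissue were compared in a fit of that tissue's 6 arrays. The difference between the responses of the tissues, and control tumor against control mammary gland, were tested in a fit of all 12 arrays with 4 groups. A total of 36 gene lists of pathways and cell types was fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. Of 867 list entries 789 had a named probe, and the 35 lists with at least 5 genes tested entered camera with a preset correlation of 0.01 between genes, adjusted over the 35 lists. The alternatives to it were camera with the correlation estimated for each list and fry with directional p-values (statmod version 1.5.0 was loaded). Within a list, single genes were also adjusted over the list alone. That adjustment does not account for the number of lists, so its calls are no separate support for the shift of a list. In tumors it also called members of lists that did not pass camera's threshold, among them 2 glucocorticoid response genes, both higher.

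Named genes in each within-tissue comparison were the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap and that were detected on all arrays of the higher group. Where fewer than 10 passed, the 10 genes of smallest p-value were given, as values that did not pass. For the difference of responses the rule took 6 genes per direction, for the tissue comparison 8 genes per direction, and for each list past camera's threshold up to 4 members with the largest change in its direction. A set of genes of glucose, insulin and fat metabolism and of the mammary gland was reported whatever the result. Hk2 and Mki67 of that set had no named probe and were not analysed here. Genes named outside this rule are said to have been chosen after their values were seen. Where a gene was not above background on any array of the lower group, the fold is a lower bound, computed from the bright group's mean against the higher of the dim probe's own signal and the lowest detected signal on each array.

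The analysis was tested on simulated log2 values of the 11767 genes with the spread of the real arrays and 50 genes changed at each of 4 sizes. For a log2 change of 1 the tumor comparison recovered 43 of 50 genes, the mammary comparison 32, the difference of responses 22 and the tissue comparison 35. For a log2 change of 2 these numbers were 49, 47, 47 and 44. Each simulation held 200 changed genes, and its noise had no outlying array. With fewer changed genes the adjustment is stricter, so these shares do not carry over to comparisons with few or no calls. Among all calls, 9 of 162 were false in the tumor comparison, 6 of 137 in the mammary comparison, 7 of 127 for the difference of responses and 11 of 150 in the tissue comparison. In the same simulations, camera found 3 of 3 lists shifted by 1 log2 unit in each comparison. Of 3 lists shifted by 0.5 log2 units it found 3 in each within-tissue comparison and 2 for the difference of responses and between tissues. Of 28 lists without a shift it called 1 in the tissue comparison and 0 in the others. The simulated genes varied independently of each other, so these list results do not carry over to lists whose genes vary together. On the real arrays the estimated correlation was 0.37 for lipogenesis genes in tumor and 0.92 for cell cycle genes in the mammary gland.

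Alternatives were normexp with offset 50 in place of neqc's background, no background correction, centring of array medians in place of quantiles, neqc within each tissue, no filter, a strict filter (detection p-value below 0.01 on at least 6 arrays), the mean of a gene's probes, the deposited normalized table, eBayes with trend and robust options, the replicate number as a block, 1 fit of all 12 arrays for both within-tissue comparisons, and leaving out each array in turn with renewed normalization of the other arrays.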

Results

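The series profiled tumors and mammary glands under hyperglycemia and normal blood glucose. PyMT mice carry the polyoma middle T oncogene in the mammary epithelium and develop mammary tumors, and PANIC-ATTAC mice carry an inducible transgene that ablates insulin-producing beta cells. Tumors of PyMT/PANIC mice were set against tumors of PyMT mice, and mammary glands of PANIC-ATTAC mice against those of wild-type mice, with 3 arrays in each group. No blood glucose or insulin value of a mouse was used here. High blood glucose cannot be told apart from the loss of beta cells in these groups, so "under hyperglycemia" names the group label. Each array gave a bead intensity for every probe, and 11767 genes were tested on the log2 scale.

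Tumor and mammary arrays were far apart, and principal component 1 held 77.3% of the variance. Pearson correlations across genes, which are not independent replicates, were 0.982 to 0.992 between tumor arrays. The array labelled wild-type mammary control replicate 1 lay between the tissues: it correlated at 0.965 to 0.986 with the tumor arrays and at 0.942 to 0.961 with the other mammary arrays. Those other mammary arrays correlated at 0.971 to 0.990 with each other and at 0.874 to 0.939 with tumors. The array had a median of 37 beads per probe, against 43 to 44 on the others. Hyperglycemic mammary replicate 3 stood apart on principal component 2, at -34.8, where the other mammary arrays lay between 1.32 and 13.5.

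**Figure D1:**
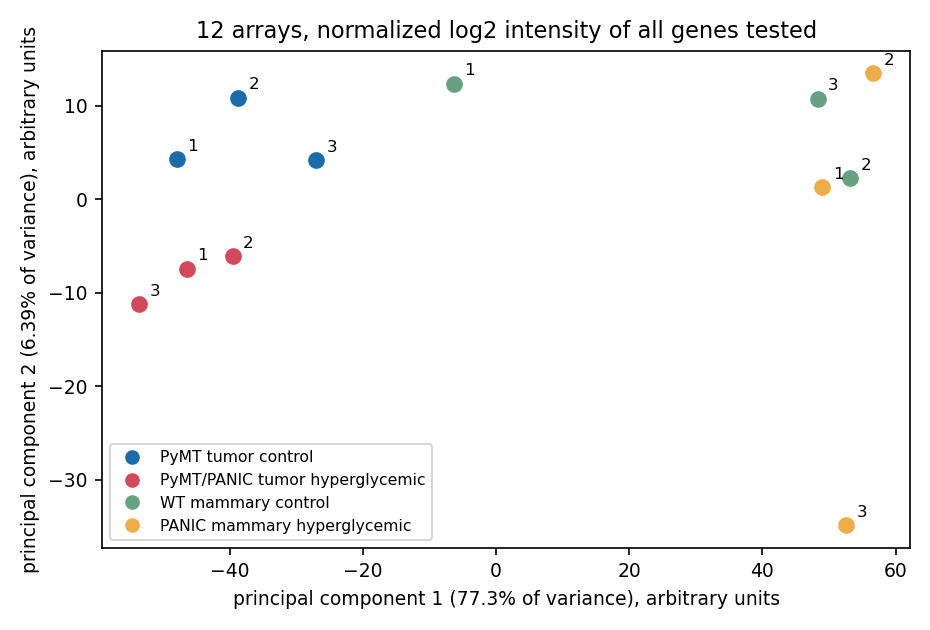
Principal components 1 (77.3% of variance) and 2 (6.39%) of normalized log2 intensity over all genes tested, in arbitrary units, with 1 point per array, coloured by group and numbered by replicate. Wild-type mammary control replicate 1 sits at -6.39 on component 1, between the tumors (-53.6 to -27.1) and the other mammary arrays (48.3 to 56.6).

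In tumors, 3 genes of fat metabolism fell under hyperglycemia, and no gene was higher past the threshold. Cidea, which encodes a lipid droplet protein abundant in brown adipocytes (Entrez Gene 12683), was 7.60-fold lower (log2 fold change -2.93 ± 0.26 SE, 3 against 3 arrays, adjusted p = 0.0296). Its log2 intensity was 9.83 ± 0.49 (SD, n = 3) in control and 6.90 ± 0.31 (SD, n = 3) in hyperglycemic tumors. Fabp3, a fatty acid binding protein of heart, muscle and brown fat (Entrez Gene 14077), was 7.20-fold lower (-2.85 ± 0.23 SE, adjusted p = 0.0296) and was detected on 1 of the 3 hyperglycemic arrays. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (Entrez Gene 20249), was 2.99-fold lower (-1.58 ± 0.16 SE, adjusted p = 0.0469). In all 3 genes every hyperglycemic array lay below every control array. At an unadjusted p below 0.05, limma gave 1042 genes, where 588 would be expected with no effect.

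The next genes by p-value did not pass. Ucp1, the uncoupling protein of brown adipocytes, had a log2 fold change of -4.08 ± 0.45 SE (adjusted p = 0.0537) and was detected on 1 of 3 hyperglycemic arrays. Paqr9 was at least 2.80-fold lower (adjusted p = 0.0517). Cpt1b, the carnitine palmitoyltransferase of muscle and brown fat, stood at -1.76, the natriuretic peptide clearance receptor gene Npr3 at -1.79 and the glycogen phosphorylase gene Pygl at -1.65, with adjusted p from 0.0609 to 0.0887. Zbtb16, a transcription factor gene induced by glucocorticoids, stood at 1.14 ± 0.13 SE and Rab26, a small GTPase gene, at 0.79 ± 0.09 SE (adjusted p = 0.0537 for both). Over 17 alternative settings Paqr9 passed in 7, Rab26 in 6, Zbtb16 and Ucp1 in 5 each, and Cpt1b, Npr3 and Pygl in 4 each, in the same directions. The other probe of Paqr9 stood at -0.35 and the other probes of Npr3 at -0.34, -0.34 and -1.30.

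**Figure D2:**
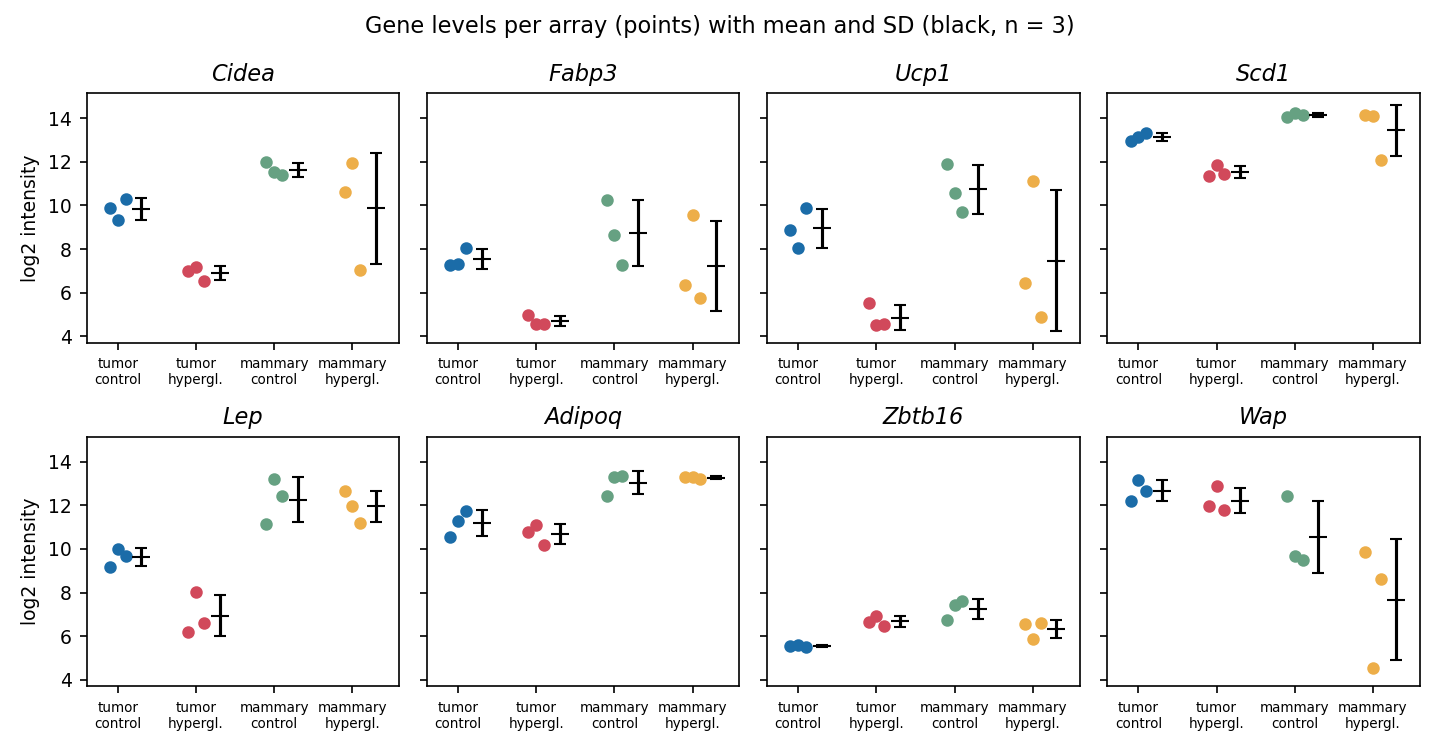
Normalized log2 intensity of 8 genes on each of the 12 arrays (points, coloured by group), with the group mean and SD (black, n = 3); the genes were chosen after their values were seen. Cidea, Fabp3, Ucp1, Scd1, Lep and Zbtb16 show no overlap between control and hyperglycemic tumors, while Adipoq and Wap overlap.

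With the preset correlation 13 lists passed camera's threshold in tumors. Of 10 splits of the 6 tumor arrays, the real one included, 5 gave at least as many, so chance cannot be excluded for their number. Genes of fatty acid and triglyceride synthesis were lower as a group in hyperglycemic tumors. All 20 measured members of the lipogenesis list had a negative log2 fold change (median -0.58, camera adjusted p = 5.6e-15), though adjusted p = 0.294 with an estimated correlation. Adjusted over the list alone, 11 of the 20 fell, against 1 over all genes. Besides Scd1, these included the triglyceride synthesis gene Dgat2 (-2.47 ± 0.37 SE), the acetyl-CoA synthetase gene Acss2 (-1.07 ± 0.16 SE) and the fatty acid elongase gene Elovl6 (-0.92 ± 0.16 SE), chosen after their values were seen. The brown adipocyte list was lower by a median of -1.22, with 8 of 10 members below 0 (camera adjusted p = 2.0e-10; adjusted p = 0.294 with an estimated correlation). Adjusted over the list alone, 6 of these 10 fell: Fabp3, Cidea, Ucp1, Cpt1b, and the muscle and heart type cytochrome oxidase subunit genes Cox7a1 and Cox8b. The general adipocyte list was lower in 17 of 17 members (median -0.67, camera adjusted p = 5.4e-09; adjusted p = 0.554 with an estimated correlation), and 6 fell when adjusted over the list alone. Among them were the hormone gene leptin, Lep (-2.67 ± 0.44 SE), the insulin-regulated glucose transporter gene Slc2a4 (-1.03 ± 0.24 SE) and the adipocyte transcription factor gene Pparg (-1.09 ± 0.26 SE, with its other probes at -0.15 and -0.11), none past the threshold over all genes. Adipoq, which encodes the adipocyte hormone adiponectin, stood at -0.50 ± 0.33 SE.

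Mitochondrial and cell division genes were lower by small amounts in hyperglycemic tumors. Oxidative phosphorylation genes were below 0 in 59 of 65 members (median -0.13, camera adjusted p = 5.7e-08; adjusted p = 0.294 with an estimated correlation) and none passed over the list alone. Examples were cytochrome c, Cycs (-0.45 ± 0.12 SE) and Cox5a (-0.35 ± 0.10 SE). In the tricarboxylic acid cycle list 18 of 20 members were below 0 (median -0.19, camera adjusted p = 6.5e-06; adjusted p = 0.211 with an estimated correlation). Citrate synthase, Cs (-0.33 ± 0.08 SE), and pyruvate carboxylase, Pcx (-0.84 ± 0.21 SE), fell when adjusted over the list alone. Cell cycle genes were below 0 in 29 of 29 members (median -0.18, camera adjusted p = 5.2e-07; adjusted p = 0.563 with an estimated correlation), with Nusap1 at -0.32 (its other probe at 0.10) and Mcm2 at -0.29. Fatty acid oxidation genes were below 0 in 17 of 24 members (median -0.13, camera adjusted p = 0.00446; adjusted p = 0.768 with an estimated correlation), and Cpt1b alone passed over the list. The mean fatty acid oxidation score per array overlapped between groups, at -0.3445 in control replicate 1 and -0.343 in hyperglycemic replicate 2.

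Lists of other cell types and signals shifted too. Endothelial genes were below 0 in 18 of 19 members (median -0.30, camera adjusted p = 4.7e-04), among them the vascular phosphatase gene Ptprb (-0.43), and extracellular matrix genes in 22 of 27 (median -0.17, camera adjusted p = 0.00818), among them Col4a2 (-0.49) and Sparc (-0.36, its other probes at -0.05 and -0.32). Both had adjusted p = 0.790 with an estimated correlation. Basal and myoepithelial genes were below 0 in 13 of 13 members (median -0.16, camera adjusted p = 0.00446; adjusted p = 0.563 with an estimated correlation) and WNT targets in 12 of 14 (median -0.14, camera adjusted p = 0.0243; adjusted p = 0.554 with an estimated correlation). Interferon response genes were above 0 in 25 of 26 members (median 0.33, camera adjusted p = 2.6e-04; adjusted p = 0.790 with an estimated correlation), with Irf7 at 1.12 ± 0.55 SE and Stat2 at 0.39 ± 0.14 SE. Their mean score per array overlapped between groups, from -0.73 to 0.18 in control and -0.53 to 0.35 in hyperglycemic tumors. Circadian clock genes were above 0 in 11 of 15 members (median 0.21, camera adjusted p = 0.0232; adjusted p = 0.585 with an estimated correlation), with Per1 at 0.53. Scores overlapped too for endothelial (-0.86 to -0.24 in control, -1.12 to -0.60 in hyperglycemic tumors) and matrix genes (-0.39 to -0.21 and -0.56 to -0.24). The same held for circadian genes (-0.35 to -0.058 and -0.071 to -0.049). Basal and WNT target scores did not overlap. Beside these shifts, control replicate 3 and hyperglycemic replicate 3 held more skeletal muscle signal (scores 0.32 and 0.25) than the other tumor arrays (-1.56 to -1.18). No member of these 6 lists passed over its list alone.

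Of the genes set in advance, Scd1 alone passed in tumors. The glucose-induced genes Txnip and Arrdc4 stood at 0.27 ± 0.19 SE and 0.33 ± 0.13 SE, and the glucose transporter gene Slc2a1 at 0.13 ± 0.14 SE. Fatty acid synthase, Fasn, was at -0.92 ± 0.26 SE, its regulator Srebf1 at -0.27 ± 0.13 SE and the pyruvate dehydrogenase kinase gene Pdk4 at -1.30 ± 0.39 SE. Insulin receptor, Insr, stood at -0.12 ± 0.11 SE, its substrate Irs2 at 0.18 ± 0.12 SE, Igf1 at -0.53 ± 0.29 SE and Igf1r at -0.26 ± 0.12 SE. Cyclin D1, Ccnd1, was at -0.14 ± 0.16 SE, and the milk protein genes Csn2 and Wap at -1.52 ± 0.86 SE and -0.46 ± 0.33 SE. Adjusted p for these ranged from 0.378 to 0.840. Lists of glycolysis (median 0.04, camera adjusted p = 0.983), of glucose-responsive targets (-0.07, 0.548) and of the insulin-like growth factor axis (-0.12, 0.248) did not pass; for glycolysis the mean over members (-0.05) had the opposite sign to the median.

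The calls of the 3 genes changed with single arrays, while their folds changed little. Without hyperglycemic tumor replicate 1, 2 or 3 none of the 3 genes passed. Without control replicate 2 Cidea alone passed, without control replicate 3 Cidea and Fabp3 passed, and without control replicate 1 there were 8 genes, these 3 included. Over the 3 left-out hyperglycemic arrays the log2 fold change was -3.05 to -2.75 for Cidea, -2.99 to -2.77 for Fabp3 and -1.74 to -1.48 for Scd1. The processing moved the folds more: over all 17 alternative settings the range was -3.18 to -2.51 for Cidea and -2.99 to -1.71 for Fabp3. For Scd1 it stayed at -1.74 to -1.48. With unchanged folds, none of the 3 passed without a detection filter (adjusted p from 0.154 to 0.155) or with all 12 arrays in 1 fit (0.999 for Cidea, Fabp3 and Scd1), and Scd1 did not with neqc within each tissue (0.05003). Without hyperglycemic replicate 3, 7 of the 13 lists no longer passed (adjusted p from 0.0575 to 0.285), the lipogenesis, brown adipocyte, adipocyte, oxidative phosphorylation, cell cycle and tricarboxylic acid cycle lists being the exceptions. The brown adipocyte median ran from -1.62 with the strict filter to -0.47 without a filter over 16 settings, and the adipocyte median from -0.99 without control replicate 1 to -0.41 without control replicate 3. Without control replicate 2 the circadian, matrix and WNT target lists did not pass (0.0555 to 0.236). The same held without control replicate 3 for the endothelial, matrix and fatty acid oxidation lists (0.0554 to 0.172), without hyperglycemic replicate 1 for the WNT target list (0.0507) and without hyperglycemic replicate 2 for the circadian list (0.0549). The matrix and WNT target lists did not pass with the mean of a gene's probes (0.0575 and 0.0612), the circadian and WNT target lists without a filter (0.0606 and 0.0833), and the circadian list with the strict filter (0.115). Medians moved by over 1.5 times for matrix (-0.080, -0.082 and -0.053 without control replicates 2 and 3 and hyperglycemic replicate 3, and -0.27 without hyperglycemic replicate 2) and fatty acid oxidation genes (-0.069 and -0.034 without control replicate 3 and hyperglycemic replicate 3, -0.21 without hyperglycemic replicate 2). They did so too for endothelial (-0.13 without control replicate 3, -0.18 without hyperglycemic replicate 3), adipocyte (-0.43 without hyperglycemic replicate 3), interferon (0.54 without control replicate 1, 0.59 without hyperglycemic replicate 1), basal (-0.082 and -0.25 without hyperglycemic replicates 1 and 2), WNT target (-0.22 without control replicate 3) and circadian genes (0.33, 0.10 and 0.14 without control replicates 1 to 3 in turn).

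In the mammary gland no single gene passed under hyperglycemia, while basal epithelial, matrix and muscle genes were higher and milk and lipid genes lower as groups by camera with the preset correlation. With an estimated correlation 0 lists passed (adjusted p from 0.537 to 0.671 for the 19 lists past camera's threshold with the preset correlation), and single arrays moved many of these medians. Limma gave 0 genes over all genes tested, 626 at an unadjusted p below 0.05 where 588 would be expected with no effect, and a smallest adjusted p of 0.786. The basal keratin gene Krt15 had a log2 fold change of 2.05 ± 0.29 SE (3 against 3 arrays) and the prostacyclin synthase gene Ptgis 1.30 ± 0.18 SE. Trim9, a ubiquitin ligase gene, stood at 1.97 ± 0.35 SE, Arsj at 1.43 ± 0.25 SE, Amn at 1.20 ± 0.19 SE and Kdelr3 at 0.84 ± 0.14 SE. The peroxisomal gene Acbd5 stood at -0.85 ± 0.14 SE, with its other probe at -0.12, and Ncan was at least 1.69-fold lower.

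Basal and myoepithelial, matrix and WNT target genes were higher as groups in the hyperglycemic mammary gland. Basal and myoepithelial genes were above 0 in 12 of 13 members (median 0.39, camera adjusted p = 4.8e-05; adjusted p = 0.537 with an estimated correlation). Adjusted over the list alone, 3 rose, Krt15, Krt5 (0.89 ± 0.17 SE) and Krt17 (0.91 ± 0.26 SE). Extracellular matrix genes were above 0 in 23 of 27 members (median 0.43, camera adjusted p = 1.7e-07; adjusted p = 0.537 with an estimated correlation), and the collagen genes Col1a2 (0.84 ± 0.14 SE) and Col6a2 (0.96 ± 0.17 SE) rose when adjusted over the list alone. WNT targets were above 0 in 12 of 14 members (median 0.42, camera adjusted p = 0.00170; adjusted p = 0.537 with an estimated correlation), with Wnt4 at 1.07 ± 0.32 SE. Beside these groups, skeletal muscle genes were above 0 in 19 of 20 members (median 1.76, camera adjusted p = 1.6e-06; adjusted p = 0.591 with an estimated correlation), with parvalbumin, Pvalb, at 3.07 ± 1.49 SE and Tnnt1 at 0.72 ± 0.26 SE. Their score was 3.34 in hyperglycemic replicate 3, 1.51 in control replicate 2 and between -1.26 and 0.94 elsewhere. Keratinocyte genes were above 0 in 6 of 7 members (median 0.46, camera adjusted p = 0.0102; adjusted p = 0.663 with an estimated correlation). Loricrin, Lor, a protein of the outer skin layer, was at least 12.9-fold higher, from high values in hyperglycemic replicates 1 and 3 (9.85 and 11.1) and not in replicate 2 (4.89). Krt10, chosen after its values were seen, lay at 11.4, 8.38 and 11.7 in hyperglycemic replicates 1 to 3. Whether the basal keratin signal came from the gland or from skin was not tested.

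Secretory epithelial and lipid genes were lower as groups in the hyperglycemic mammary gland by camera with the preset correlation. Mean scores per array overlapped between groups for milk, luminal, lipogenesis and brown adipocyte genes, and did not for cholesterol synthesis genes. Hyperglycemic replicate 1 scored -0.35 for milk and -0.38 for luminal genes, above control replicate 2 (-0.59 and -0.49). For brown adipocyte genes hyperglycemic replicate 2 (1.63) lay above control replicate 2 (1.13). Milk protein and alveolar genes were below 0 in 16 of 17 members (median -0.81, camera adjusted p = 4.9e-06; adjusted p = 0.537 with an estimated correlation), with alpha-lactalbumin, Lalba, at -1.91 ± 0.67 SE and Btn1a1, of the milk fat globule, at -1.44 ± 0.48 SE. Luminal epithelial genes were below 0 in 16 of 20 members (median -0.50, camera adjusted p = 0.00135; adjusted p = 0.591 with an estimated correlation), among them Elf3 (-0.63). Cholesterol synthesis genes were below 0 in 15 of 16 members (median -0.48, camera adjusted p = 3.0e-06; adjusted p = 0.537 with an estimated correlation), with Cyp51 at -0.47 ± 0.14 SE. Lipogenesis genes were below 0 in 16 of 20 (median -0.38, camera adjusted p = 0.00338; adjusted p = 0.663 with an estimated correlation), and the desaturase gene Scd2 (-1.07 ± 0.22 SE) fell when adjusted over the list alone. Brown adipocyte genes were below 0 in 9 of 10 members (median -0.84, camera adjusted p = 0.00385; adjusted p = 0.591 with an estimated correlation), with Ucp1 at -3.26 ± 1.53 SE. The general adipocyte list did not pass (median 0.09, camera adjusted p = 0.541).

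Other shifts covered energy metabolism and immune cells. Oxidative phosphorylation (61 of 65 members below 0, median -0.12, camera adjusted p = 4.4e-05), tricarboxylic acid cycle (18 of 20, -0.21, 0.00138) and fatty acid oxidation genes (20 of 24, -0.19, 0.00502) were lower, each with adjusted p = 0.663 with an estimated correlation. Hyperglycemic replicate 2 went the other way, with the highest score of all mammary arrays for these lists (0.28, 0.56 and 0.68 in turn). The highest control scores were 0.20, 0.46 and 0.54. Scores of the glucocorticoid, macrophage, B cell and neutrophil lists below also overlapped between groups. Glycolysis genes were below 0 in 14 of 19 members, with aldolase, Aldoa, at -0.40 ± 0.13 SE (median -0.22, camera adjusted p = 0.0102), and unfolded protein response genes in 18 of 22, with Atf3 at -0.72 ± 0.16 SE (median -0.09, camera adjusted p = 0.00268), both with adjusted p = 0.537 with an estimated correlation. Glucocorticoid response genes were below 0 in 15 of 17 members (median -0.12, camera adjusted p = 0.0391; adjusted p = 0.591 with an estimated correlation), with Zbtb16 at -0.91 ± 0.29 SE. With the strict detection filter the glucocorticoid list did not pass (camera adjusted p = 0.0533). Macrophage genes were above 0 in 18 of 23 members (median 0.28, camera adjusted p = 0.0121; adjusted p = 0.671 with an estimated correlation), with Marco at 0.83, and B cell genes in 13 of 14 (0.34, 0.0123; adjusted p = 0.663 with an estimated correlation). Neutrophil genes were above 0 in 9 of 12 (median 0.44, camera adjusted p = 0.00255; adjusted p = 0.537 with an estimated correlation), with S100a9 at 0.96, but their median was -0.06 with the strict detection filter.

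Of the genes set in advance, none passed in the mammary gland. Wap stood at -2.85 ± 1.44 SE, Csn2 at -1.78 ± 1.31 SE, Fasn at -1.01 ± 0.63 SE, Srebf1 at -0.71 ± 0.24 SE, Pdk4 at -0.73 ± 0.38 SE and Scd1 at -0.70 ± 0.53 SE. Lep was at -0.32 ± 0.57 SE, Slc2a4 at -0.36 ± 0.49 SE, Adipoq at 0.24 ± 0.26 SE, Igf1 at 0.44 ± 0.45 SE and Igf1r at 0.17 ± 0.25 SE. Txnip, Arrdc4, Slc2a1, Insr, Irs2 and Ccnd1 lay between -0.22 and 0.37. Adjusted p for these ranged from 0.848 to 0.978.

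**Figure D3:**
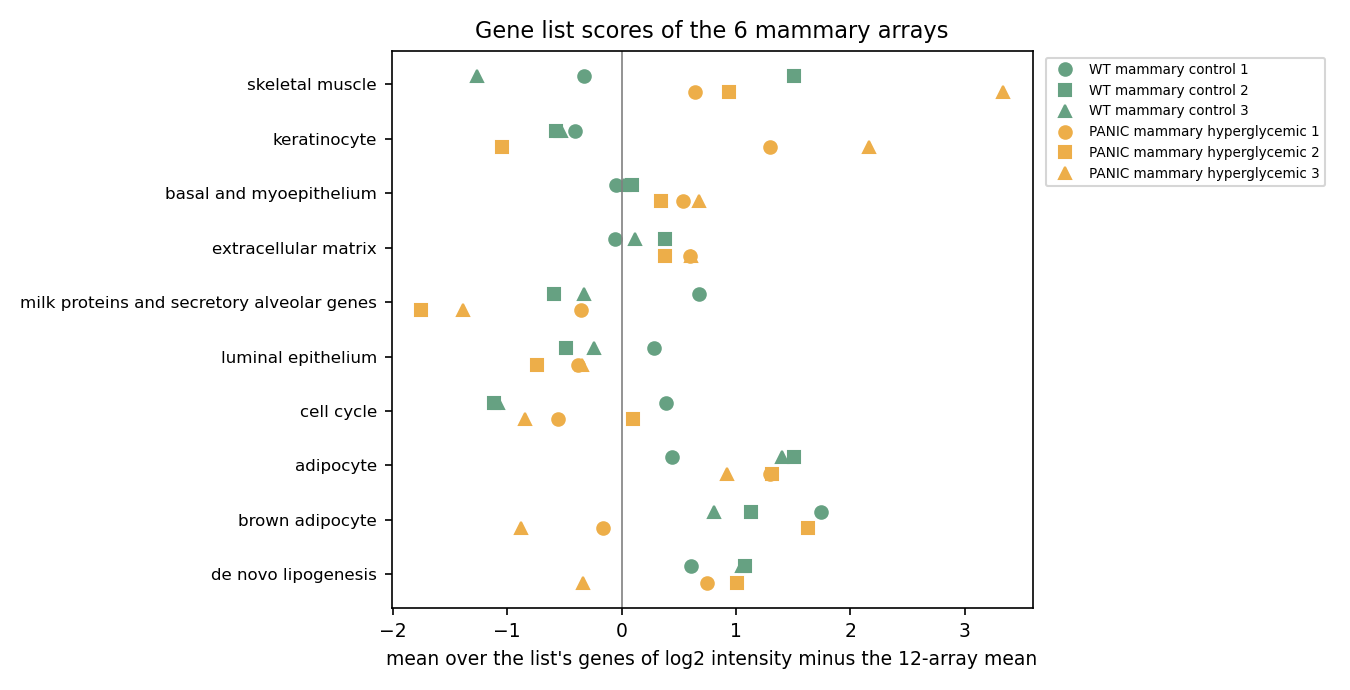
Mean over each list's genes of log2 intensity minus the mean of all 12 arrays, for 10 gene lists on the 6 mammary arrays, coloured by group with a symbol per replicate. Hyperglycemic replicate 3 is highest for skeletal muscle (3.34) and lowest for lipogenesis (-0.34), and control replicate 1 is highest for milk (0.68) and cell cycle (0.39) genes.

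Single arrays decided many of the mammary list shifts. Without hyperglycemic replicate 3, 10 of 19 lists no longer passed (adjusted p from 0.0678 to 0.654), namely lipogenesis, brown adipocyte, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, glucocorticoid, keratinocyte, macrophage and B cell genes. Medians then were -0.0063 for lipogenesis, -0.34 for brown adipocyte, -0.026 for oxidative phosphorylation, -0.034 for tricarboxylic acid cycle, -0.060 for fatty acid oxidation, -0.14 for glycolysis, 0.19 for keratinocyte and 0.042 for macrophage genes, and 0.84 for muscle and -0.28 for cholesterol genes, which still passed. Without control replicate 1, the luminal, B cell, macrophage, glucocorticoid and unfolded protein lists did not pass (0.0858 to 0.929), with medians of -0.13 for luminal, 0.043 for B cell and 0.14 for macrophage genes. The matrix, WNT target, milk and cholesterol lists still passed without that array, but with medians of 0.21, 0.19, -0.46 and -0.31. Its milk score was 0.68 against -0.59 and -0.33 in the other control glands. Lipogenesis and keratinocyte medians were larger without it (-0.65 and 0.93). Without control replicate 2, 4 lists did not pass (0.0641 to 0.120). Without hyperglycemic replicate 1, 3 lists (0.0634 to 0.0635) did not. Without hyperglycemic replicate 2 the glucocorticoid list (0.238) did not pass, while Krt10 and Lor then passed as single genes. Without hyperglycemic replicate 2 the medians of the lipogenesis (-0.73), brown adipocyte (-1.41), oxidative phosphorylation (-0.25), tricarboxylic acid cycle (-0.41), fatty acid oxidation (-0.40), glycolysis (-0.34), keratinocyte (1.07) and macrophage lists (0.51) were over 1.5 times as large. The neutrophil median was 0.22 without hyperglycemic replicate 1, the milk median -1.28 without control replicate 2, and the muscle and B cell medians 1.16 and 0.61 without control replicate 3. Glucocorticoid medians were -0.19 and -0.059 without hyperglycemic replicates 1 and 2 and -0.18 without control replicate 3. Unfolded protein medians were -0.14 without hyperglycemic replicate 1 and -0.20 without control replicate 2.

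**Figure D4:**
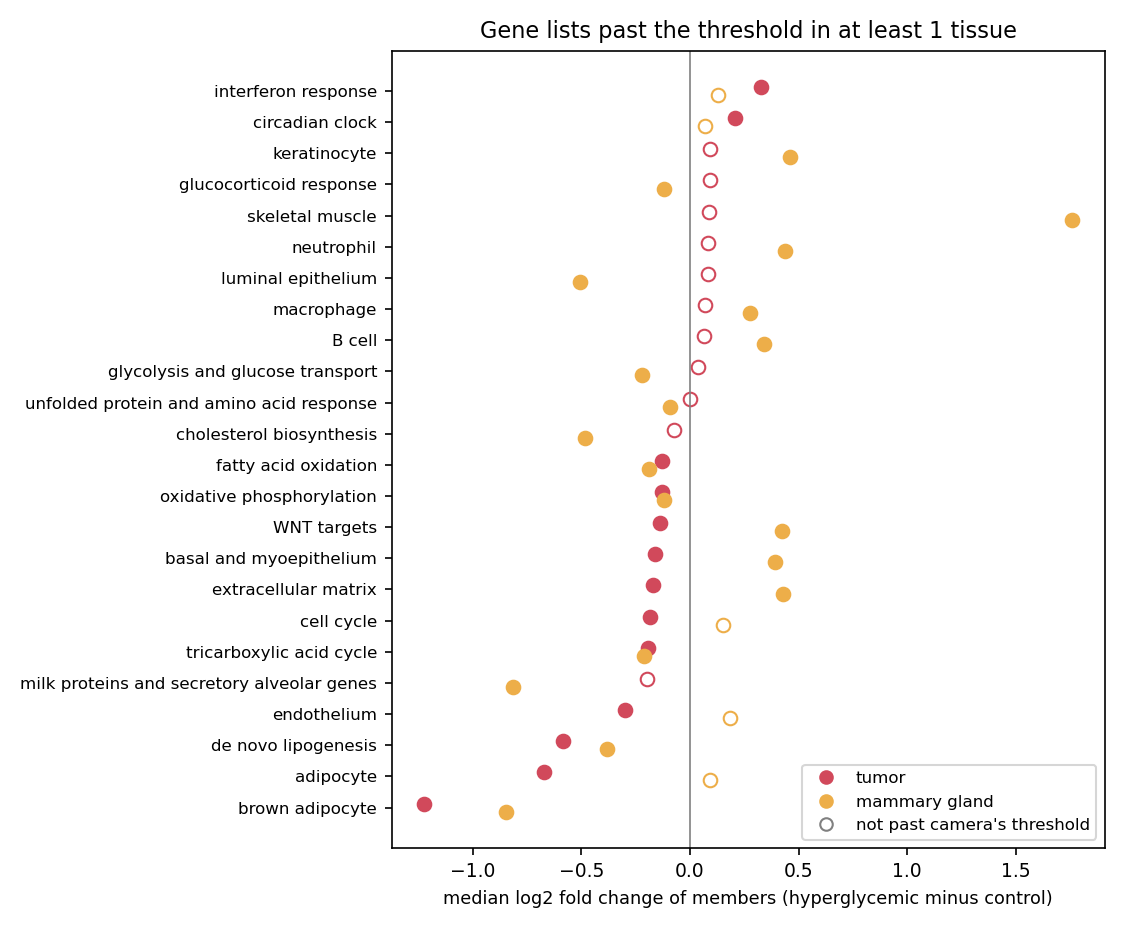
Median log2 fold change (hyperglycemic minus control) of the members of each gene list that passed camera's threshold in at least 1 tissue, in tumor and mammary gland; open points did not pass in that tissue. Brown adipocyte and lipogenesis genes lie below 0 in both tissues, and matrix, basal and WNT target genes lie on opposite sides of 0.

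Matrix and basal epithelial genes were lower as groups in hyperglycemic tumors and higher in hyperglycemic mammary glands, and the difference of responses passed camera's threshold with the preset correlation. The tumor response minus the mammary response was below 0 in 23 of 27 extracellular matrix genes (median -0.65, camera adjusted p = 1.7e-08; adjusted p = 0.583 with an estimated correlation) and, adjusted over the list alone, lower for Col1a1, Col1a2 and Col6a2 (-1.18 ± 0.24 SE for the last). It was below 0 in 13 of 13 basal and myoepithelial genes (median -0.55, camera adjusted p = 9.9e-07; adjusted p = 0.163 with an estimated correlation), where Krt15 (-2.69 ± 0.40 SE) and Krt5 (-1.12 ± 0.21 SE) were lower when adjusted over the list alone. The same held for WNT targets in 13 of 14 members, with Wnt4 at -1.44 ± 0.39 SE (median -0.56, camera adjusted p = 1.7e-04; adjusted p = 0.375 with an estimated correlation). Adipocyte genes had a median difference of -0.75 (15 of 17 below 0, camera adjusted p = 7.1e-05; adjusted p = 0.719 with an estimated correlation), with Lep at -2.35 ± 0.81 SE and Pparg at -1.28 ± 0.41 SE (its other probes at -0.07 and -0.08). For the brown adipocyte and lipogenesis lists the difference did not pass (medians -0.40 and -0.29, camera adjusted p = 0.498 and 0.195).

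The other lists past the threshold were skeletal muscle (median -1.75, camera adjusted p = 4.4e-04; adjusted p = 0.753 with an estimated correlation), endothelium (-0.49, 0.00172; adjusted p = 0.770 with an estimated correlation) and cell cycle genes (-0.33, 0.0269; adjusted p = 0.812 with an estimated correlation). Above 0 were milk and alveolar (0.73, 0.00263), cholesterol synthesis (0.39, 0.00306), luminal (0.55, 0.00306), glucocorticoid response (0.32, 0.0118) and unfolded protein response genes (0.12, 0.0190), each with adjusted p = 0.719 with an estimated correlation. In the glucocorticoid list Zbtb16 was higher in the tumor response when adjusted over the list alone (2.05 ± 0.34 SE). No single gene passed over all genes with limma: 915 had an unadjusted p below 0.05 and the smallest adjusted p was 0.166, shared by Krt15, Zbtb16, Amn (-1.44), Acbd5 (1.11, its other probe at -0.02), the protease gene Adamts18 (-1.97 ± 0.29 SE) and the TGF-beta-induced gene Pmepa1 (1.21 ± 0.19 SE). Across genes, the log2 fold changes of the tissues had a Pearson correlation of -0.05 and a Spearman correlation of -0.10, and 46.9% of genes had the same sign. Without mammary control replicate 1, 3 genes passed (Irak2, Krt15, Zbtb16), and 5 of the 12 lists, the milk, luminal, endothelium, glucocorticoid and unfolded protein lists, did not (adjusted p from 0.0608 to 0.246). Without hyperglycemic mammary replicate 2, 4 genes passed (Krt10, Lor, Ncan and Serpinb11), 19 lists passed in all, and the cell cycle list did not (0.576). The cell cycle list also did not pass without mammary control replicate 2 (0.618) or 3 (0.580), tumor control replicate 2 (0.0767) or hyperglycemic tumor replicate 2 (0.0775). Skeletal muscle did not pass without hyperglycemic mammary replicate 3 (0.1002, median -0.81) or mammary control replicate 3 (0.0767), and cholesterol synthesis did not without hyperglycemic mammary replicate 3 (0.0884). The unfolded protein list did not pass without tumor control replicate 1 (0.0531) or hyperglycemic tumor replicate 2 (0.0704) or 3 (0.175), the endothelial list without tumor control replicate 3 (0.0547) and the glucocorticoid list without hyperglycemic tumor replicate 2 (0.0547). Without mammary control replicate 1 the adipocyte median was -0.44 and the cell cycle median -0.79, and both lists still passed (adjusted p = 0.0314 and 5.4e-18), while the milk (0.22), luminal (0.20), endothelial (-0.19) and glucocorticoid medians (0.15) shrank. The cell cycle median was -0.056 without hyperglycemic mammary replicate 2, -0.12 without either mammary control replicate 2 or 3 and -0.54 without hyperglycemic mammary replicate 3, where the cholesterol median was 0.17. Without tumor control replicate 3 the muscle, cholesterol and glucocorticoid medians were -0.98, 0.25 and 0.16, and without mammary control replicate 3 the muscle median was -1.10. The glucocorticoid median was 0.21 without hyperglycemic tumor replicate 3, and the unfolded protein median 0.040 without that array and 0.21 without hyperglycemic tumor replicate 1.

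Control tumors differed from control mammary glands in 4561 genes, 2497 higher and 2064 lower in tumor, in proliferation, fat, immune and vascular genes. Cell cycle genes were higher in 29 of 29 members, 24 past the threshold over all genes (median 1.23, camera adjusted p = 8.7e-07; adjusted p = 0.567 with an estimated correlation), with Cdc20 at 1.73 ± 0.46 SE and Aurkb at 1.70 ± 0.46 SE. All 17 adipocyte genes were lower and passed (median -2.06, camera adjusted p = 2.0e-10; adjusted p = 0.483 with an estimated correlation), with perilipin, Plin1, 6.33-fold, the glycerol channel gene Aqp7 5.74-fold and the lipid droplet gene Cidec 5.59-fold lower. The rule named the methyltransferase gene Inmt (11.2-fold lower, log2 fold change -3.48 ± 0.48 SE), Timp4 (10.7-fold), Mmd2 (10.5-fold), Cxcl15 (8.15-fold), the liver-type glycogen synthase gene Gys2 (7.22-fold), Ppp1r1a (7.03-fold) and gelsolin, Gsn (6.92-fold, a log2 fold change of -2.79 with its other probe at -0.21), with Cyp3a57 at least 7.59-fold lower. Higher in tumor were the glutamine transporter gene Slc38a3 (5.23-fold, 2.39 ± 0.50 SE), Scrg1 (5.16-fold), the casein gene Csn1s2b (4.84-fold), Psapl1 (4.65-fold), Scgb1c1 (4.55-fold), Bglap2 (4.07-fold), Dyrk3 (3.96-fold) and Tmprss4 (3.90-fold).

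Immune and vascular lists were lower in tumor. T cell genes passed in 15 of 18 members below 0 with 1 above (median -1.65, camera adjusted p = 5.7e-08), B cell genes in 13 of 14 (-1.59, 8.7e-07), endothelial genes in 18 of 19 (-1.27, 1.8e-08), mast cell genes in 6 of 7 (-2.04, 0.00869) and antigen presentation genes in 8 of 12 (-0.85, 6.5e-05). Examples were Cd3d (-2.32 ± 0.40 SE), Cd79b (-2.13 ± 0.36 SE), Vwf (-1.57 ± 0.37 SE) and Cpa3 (-2.20 ± 0.48 SE), and each of these lists had adjusted p = 0.483 with an estimated correlation. Fatty acid oxidation (19 of 24 lower, median -0.74, camera adjusted p = 8.1e-07), tricarboxylic acid cycle (13 of 20, -0.52, 3.6e-06), lipogenesis (11 of 20 lower and 2 higher, -1.56, 2.5e-05), matrix (15 of 27 lower and 2 higher, -0.59, 2.3e-04) and insulin-like growth factor axis genes (8 of 17 lower and 3 higher, -0.49, 0.0461) were lower, each again with adjusted p = 0.483 with an estimated correlation. Among them were Decr1 (-1.62 ± 0.25 SE), Mlxipl, which encodes the carbohydrate-responsive factor ChREBP (-2.18 ± 0.34 SE), and Igf1 (-1.79 ± 0.42 SE). Oxidative phosphorylation (median -0.24, camera adjusted p = 3.6e-05), interferon response (-0.40, 0.00523) and macrophage genes (-0.39, 0.0136) were lower and ribosomal protein genes higher (0.19 against 0.07 over all genes, 0.00592), each with adjusted p = 0.579 with an estimated correlation. Brown adipocyte genes were lower (-1.35, 0.00592; adjusted p = 0.523 with an estimated correlation).

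Tissue and slide cannot be told apart in this comparison, and the scaling moved its balance: with neqc within each tissue 3468 genes were higher and 1880 lower (64.8% higher, against 54.7%), and the median of all genes moved from 0.07 to 0.13. The count was 6106 without control mammary replicate 1, 1660 without control mammary replicate 3, 1697 without control mammary replicate 2, 2201 without control tumor replicate 1 and 2517 without control tumor replicate 2. Scrg1, Psapl1, Bglap2, Tmprss4, Cdc20, Aurkb and Igf1 were each above the threshold when at least 1 of these arrays was left out (adjusted p from 0.0505 to 0.157). Of the lists, the insulin-like growth factor axis did not pass in 7 of 22 settings (adjusted p from 0.0501 to 0.0819), among them leaving out control tumor replicate 1 or 3, control mammary replicate 2 or any hyperglycemic mammary array. The brown adipocyte and interferon lists did not pass without control mammary replicate 1 (0.0682 for both), nor the macrophage list without control tumor replicate 2 (0.0636). Control mammary replicate 1, which lay between the tissues, is part of all tissue folds above. Without it, medians were larger in size for cell cycle (1.80), adipocyte (-2.29), T cell (-2.04), B cell (-1.96) and endothelial genes (-1.59). Smaller in size were the brown adipocyte (-1.18), interferon (-0.28) and fatty acid oxidation medians (-0.72). The interferon median was -0.74, -0.26 and -0.23 without control tumor replicates 1 to 3 in turn, and the insulin-like growth factor axis median -0.75 and -0.31 without control mammary replicates 1 and 2. Bglap2 had a log2 fold change of 1.24 without control tumor replicate 2.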

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

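The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. The responses of 12 gene lists differed between tumor and mammary gland by camera with the preset correlation, and 0 lists did with an estimated correlation (adjusted p from 0.163 to 0.812 for these 12). The differences are given as the median over genes of tumor response minus mammary response on the log2 scale. The difference was -0.65 for extracellular matrix, -0.55 for basal and myoepithelial, -0.75 for adipocyte, -0.56 for WNT target, -1.75 for skeletal muscle, -0.49 for endothelial and -0.33 for cell cycle genes (-0.79 without mammary control replicate 1). It was 0.73 for milk protein and alveolar, 0.39 for cholesterol synthesis, 0.55 for luminal epithelial, 0.32 for glucocorticoid response and 0.12 for unfolded protein response genes. Of 100 splits of the arrays within tissues, 61 gave at least 12 lists, with at most 23 in another split, so chance cannot be excluded for the number of lists. For single genes all 100 splits gave at least the real count of 0, with at most 4 in another split.

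The array labelled wild-type mammary control replicate 1 lay between tumors and the other mammary arrays. A tumor sample with as little fat as the 6 tumors, under a mammary label, is argued against: 17 of 17 adipocyte genes lay above all 6 tumor arrays. However, 14 of the 17 lay below all 5 other mammary arrays. A tumor taken with more surrounding fat cannot be excluded by these genes, since their level depends on the fat taken along. A gland with more of the same luminal epithelium is also argued against: of 4 luminal genes lower in tumor (Foxa1, Cited1, Esr1 and Pgr), 3 lay below every other mammary array, Foxa1 at 7.46 against at least 8.84, while 14 of the 16 other luminal genes lay above every other mammary array. A mixture of tumor and mammary RNA or tissue is consistent with the values: the median share of the way from mammary to tumor was 0.625 over 921 tumor-high genes and 0.728 over 1427 mammary-high genes, a difference of 0.103. A gland in another developmental or disease state was not tested and stays open.

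Brown adipocyte and lipogenic genes were lower in hyperglycemic tumors. The brown adipocyte genes fell further than the adipocyte genes: their score minus the adipocyte score was lower by -1.14 log2 units (0.57 ± 0.43 in control and -0.57 ± 0.41 in hyperglycemic tumors, SD, n = 3, with no overlap). The scores used 7 brown adipocyte and 14 adipocyte genes that the lists did not share. All were detected on all 3 control tumors, the group where these genes were higher, a filter that can enlarge the difference. Over all 10 and 17 members the median log2 fold changes were -1.22 and -0.67. Less adipose tissue of any kind as the whole cause is therefore not excluded for the brown adipocyte genes. For the lipogenic genes the same difference was 0.12 and the arrays overlapped, so less adipose tissue and lower expression per cell cannot be told apart. Fewer brown adipocytes in the samples also stay open, since 6 of the 7 brown adipocyte genes detected in all control tumors had a negative log2 fold change and bulk arrays hold no measure of cell shares. Of the 10 brown adipocyte genes 2 were in another list and 5 were detected on all 6 tumor arrays, and 14 of 17 adipocyte genes were so detected. An effect of hyperglycemia on tumor or fat cells, the loss of insulin-producing beta cells and the PANIC transgene itself stay open as untested. The design cannot tell these apart.

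Skeletal muscle genes were higher in the hyperglycemic mammary gland. Muscle carried along with some glands is consistent with the values: 18 of the 20 genes peaked in hyperglycemic replicate 3, and in 17 of 20 control replicate 2 was next. A rise in every hyperglycemic gland stays open: 1 of 20 muscle genes had all 3 hyperglycemic arrays above all 3 control arrays, but 19 of 20 did when control replicate 2 was left out, so that array alone decided the count. Acta1, chosen after its values were seen, lay at 10.1, 10.4 and 13.1 in hyperglycemic replicates 1 to 3 and at 8.64, 11.4 and 5.95 in control replicates 1 to 3, and Atp2a1 at 9.04, 9.84 and 12.7 against 8.004, 10.2 and 5.06. None of the 20 genes was in another list, and 11 were detected on all 6 mammary arrays.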

How the results depend on the processing

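All alternatives were planned before the data were examined. The 3 arrays per group allow 10 splits for each 2-group comparison, too few for a share below 0.05. For tumor genes the real count was 3 (2 of 10 splits as large) and the highest other 6, in the split of control replicate 1 with hyperglycemic replicates 2 and 3. For mammary genes it was 0 (10 of 10; highest other 0) and for the tissue comparison 4561 (1 of 10; highest other 0). For lists it was 13 in tumor (5 of 10, highest other 16), 19 in the mammary gland (4 of 10, highest other 20) and 17 between tissues (1 of 10, highest other 15). Other splits thus gave about as many lists as the real groups within each tissue, and chance cannot be excluded for these 2 numbers of lists. Genes changed in tumor numbered 8 with normexp and offset 50, 9 without background correction, 10 with centred medians, 7 with the strict filter, 12 with the authors' table and 9 with trend and robust options, each including Cidea, Fabp3 and Scd1. Of these, 1 was higher with normexp (Rab26) and 2 in each of the other settings (Rab26 and Zbtb16). They numbered 2 with neqc within each tissue, where Scd1 did not pass (adjusted p = 0.05003), and 0 without a filter and with all 12 arrays in 1 fit, which gave 1 mammary gene (Ncan). With the replicate number as a block, tumor genes numbered 0 against 3. Mammary genes and genes for the difference of responses stayed at 0. There limma's smallest adjusted p fell from 0.786 to 0.238 and from 0.166 to 0.0800. The labels do not say whether the numbers pair the samples. Deviations of same-numbered arrays correlated at -0.18, 0.09 and -0.31 in tumor and 0.10, -0.03 and -0.08 in the mammary gland, too few values to settle it. With an estimated correlation 0 lists passed in each of the 4 comparisons; fry gave 3 in tumor (brown adipocyte, oxidative phosphorylation, tricarboxylic acid cycle), 0 in the mammary gland, 1 for the difference of responses (basal and myoepithelial) and 18 between tissues. Leaving out each array gave 0 (without hyperglycemic tumor replicate 3) to 8 (without control tumor replicate 1) tumor genes. It gave 1 gene without control tumor replicate 2 (Cidea). Without hyperglycemic tumor replicates 1 and 2 it gave 1 gene each (B4galnt2 and Mup5), both higher and neither called on all arrays. It gave 0 to 2 mammary genes (2 without hyperglycemic mammary replicate 2). It gave 0 to 4 genes and 9 to 19 lists for the difference of responses (3 genes and 9 lists without control mammary replicate 1, 4 genes and 19 lists without hyperglycemic mammary replicate 2). It gave 1660 (without control mammary replicate 3) to 6106 (without control mammary replicate 1) genes between tissues. The correlation of responses ran from -0.22 without hyperglycemic mammary replicate 3 to 0.0917 without control mammary replicate 1, with 0.0808 without hyperglycemic mammary replicate 2 and 0.0515 without control tumor replicate 3. Genes whose sign turned had not passed: Slc2a1 in tumor (-0.026 to 0.23 over left-out arrays) and, in the mammary gland, Irs2 (-0.080 to 0.36), Igf1 (-0.11 to 0.75), Igf1r (-0.11 to 0.35), Adipoq (-0.064 to 0.41), Txnip (-0.34 to 0.057), Lep (-0.86 to 0.15) and Insr (-0.19 to 0.13, and 0.00148 with centred medians). The neutrophil list in the mammary gland turned to -0.0618 with the strict filter, which left 6 of its genes. With centred medians the tissue comparison had 3066 higher and 1853 lower genes and a median of all genes of 0.12. In none of these was the cause tested further. Genes near background, such as Fabp3 and Ucp1 in hyperglycemic tumors, have folds limited by the signal over background.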

Other observations

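All per-array values in this part were chosen after the results were seen. The brown adipocyte genes varied widely between hyperglycemic mammary glands, with replicate 2 near the control glands and replicate 3 far below them. Ucp1 had a log2 intensity of 11.9, 10.6 and 9.72 in the control glands and 6.44, 11.1 and 4.88 in the hyperglycemic glands, replicates 1 to 3 in turn. Cidea ran from 11.39 to 11.99 in control glands and lay at 10.59, 11.96 and 7.05 in hyperglycemic glands, while Adipoq lay between 13.2 and 13.3 in all 3 hyperglycemic glands. The general adipocyte score of hyperglycemic replicate 3 was 0.92, against 1.30 and 1.31 in the other hyperglycemic glands.

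Hyperglycemic mammary replicate 2 had the lowest milk gene score of all mammary arrays (-1.75), with Wap at 4.56 and Lalba at 4.48, and the highest cell cycle score of the hyperglycemic glands (0.10), with the DNA topoisomerase gene Top2a at 9.12 against 8.31 and 7.83. The interferon score of hyperglycemic mammary replicate 3 was 1.17, above every other array (-0.73 to 0.39). Zbtb16 lay at 5.50 to 5.58 in control tumors and at 6.46 to 6.93 in hyperglycemic tumors, and at 6.75 to 7.59 in control and 5.87 to 6.59 in hyperglycemic glands, so it was higher under hyperglycemia in tumor and lower in the mammary gland without overlap in either tissue.

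Among the 3651 kept probes without a single gene name, 1 was lower in hyperglycemic tumors and limma gave 0 in the mammary gland, where 192 had an unadjusted p below 0.05.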
